A study of Mus musculus with 12 samples.

How the data were processed

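ATAC-seq libraries of mouse cells were analysed from the peak list of each library. Per the labels' protocols, cells were opened with digitonin while the transposase TDE1 cut their DNA, and the libraries were sequenced single-end on an Illumina HiSeq. The genotype label gave the groups Wt, Wt_IGF1, EF, EF_IGF1 and EF_IGF1_xeno, and replicates were numbered 1 to n within a group. Line names came from the titles and flowcells from the labels. What the abbreviations stand for is not given in the sources used here. MACS2 (no version given) and the build GRCm38.p3 are named in the submitters' processing notes. The aligner, read filters, any shift of reads for the transposase, caller options and any control are not given in the sources used here.

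Each library had its own list, so the authors called peaks per library. The deposited lists hold, for each peak, a fold over local background (a ratio), the −log10 of the p-value and of the q-value, a score that is 10 times the −log10 q, and positions. These values are the authors' own for a peak and were used only to describe, rank or filter peaks within a list. The lowest −log10 q was between 2.03 and 2.60. Peaks on chromosomes 1 to 19 and X were used, and 23 to 43 peaks per library on other sequences were left out. Read totals per library are not given in the sources used here, so the number of peaks and the genome background described next stand for depth.

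The fold and the p-value of a peak were solved together for the reads at its summit and for its local background, taking the fold as (reads + 1) over (background + 1) and the p-value as the upper Poisson tail. A whole number of reads solved 100% of the peaks in every library within 0.001 of the deposited −log10 p. The lowest background of a library is its genome background, which grows with the number of reads and the fragment extension; it ran from 0.574 (Wt replicate 3) to 2.29 (Wt replicate 1). Wt replicate 1 thus had the highest genome background and the fewest peaks.

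Overlapping peaks (at least 1 bp) of all 12 libraries were merged into regions, and a region counted as called in a library when a peak of that library overlapped it. In EF against Wt, gained regions were called in at least 3 of 4 EF and 0 of 4 Wt libraries, and lost regions the reverse. With IGF1 in EF, the rule was 2 of 2 against 0 of 2 within flowcell BSF_1013. For the single libraries it was called there and in none of the reference libraries, or the reverse. No test of single regions was made, since 4 against 4 calls cannot pass a correction over all regions. The counts of EF against Wt were set among the 35 splits of the 8 libraries into 4 and 4, comparing larger with larger direction, smaller with smaller, and the sums, and among the 18 of these splits that put 2 libraries of each flowcell on each side. Peaks per library, the share near gene ends and the Jaccard contrast were tested by exact permutation (70 label orders or 35 splits). Groups, comparisons and the ranking of the EF counts among the splits were fixed before the data were examined; which direction or sum of a split to compare, and the balance by flowcell, were chosen after.

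A table of RefSeq genes of GRCm38.p6 gave 21631 protein-coding genes on the chromosomes used; p3 and p6 share the coordinates of the chromosomes. The table holds no strand and no sequence. The planned distance to a transcription start was therefore replaced by the distance to the nearest gene interval (at most 100 kb), and the promoter class by summits within 1 kb of either end of a gene. The planned shares of sequence motifs need the genome sequence and were not analysed here.

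The 20 gene lists were EWS::FLI1 targets of human Ewing sarcoma, YAP and TEAD targets, Hippo core, IGF pathway, osteogenic, chondrogenic, adipogenic, mesenchymal stem and limb, posterior HOX, anterior HOX, extracellular matrix and mesenchymal, inflammatory and AP-1, tumour suppressors and cell cycle, WNT, SHH and BMP, and 6 marker lists (hematopoietic, endothelial, muscle, epithelial, neural, smooth muscle and pericyte). A list's share of gained and of lost regions was compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 20 lists within a comparison. Regions are not independent replicates, so this test compares these sets of regions. As an alternative added after the data were seen, a list was set against 10000 random lists of genes with matching numbers of regions. In each direction of a comparison the 10 genes with most regions were named (5 for IGF1 in Wt), leaving out unnamed gene models, with up to 4 members of each list, and Yap1, Igf1, Igf1r, Nkx2-2, Nr0b1, Cdkn2a and Prrx1 whatever their values. Not every list member so chosen is given below. The region given for a gene is the one with the highest −log10 p of that direction.

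Held-out calls carry exact Clopper-Pearson intervals at 95%. Stricter peaks (−log10 q of 5 or more), windows of 250 bp each side of the summits, the top 20000 peaks, another overlap, single flowcells, merged lines and each library left out in turn were run as alternatives. On simulated calls for the 153346 regions of the EF comparison, 189 of 200 planted gained regions were found, where the rule lets 189.5 be expected, and the pileup was found for 10409 of 10409 simulated peaks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.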

Results

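Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in mouse cells that the labels call MSCLCs. The series title places them among bone mesenchymal stem cells, and names EWS::FLI1, the fusion oncogene of Ewing sarcoma, together with YAP1 and IGF-1. The labels give 5 genotype groups over 12 libraries: Wt (n = 4), Wt_IGF1 (n = 1), EF (n = 4), EF_IGF1 (n = 2) and EF_IGF1_xeno (n = 1). Titles add a line name, S_220 or S_221 for every EF, EF_IGF1 and EF_IGF1_xeno library, so the 4 EF libraries came from 2 lines. Replicates 1 and 2 of Wt and of EF were sequenced on flowcell BSF_0654, and the other 8 libraries on flowcell BSF_1013. Nothing in the labels says that replicates came from separate animals, so the p-values of permutation tests measure the spread between these libraries. Those of the gene lists compare sets of regions or of genes and measure no spread between libraries.

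Between 7748 (Wt replicate 1) and 83718 peaks (Wt_IGF1) were listed per library. The EF group held 49983 ± 16617 peaks (SD, n = 4) and the Wt group 48825 ± 27883 (SD, n = 4), a difference smaller than the spread (exact two-sided permutation test, p = 0.943, with 0.0286 the smallest p that 4 against 4 allows). On flowcell BSF_1013 alone the means were 60082 in EF and 63514 in Wt. Peaks of all libraries were merged into 153346 regions of GRCm38, of which 5784 were called in all 12 libraries and 55661 in 1 library. A protein-coding gene lay within 100 kb of 89.0% of them. Summits within 1 kb of an end of a protein-coding gene made up 23.8% ± 6.25 of the peaks in EF and 31.9% ± 23.8 in Wt (SD, n = 4 each, exact permutation test, p = 0.857). Wt replicate 1, with the fewest peaks, had 67.6% of its summits there. The mean shares on flowcell BSF_1013 were 20.3% in EF and 19.4% in Wt, the other direction.

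Similarity by line name depended on the measure. EF replicates 1 and 3, both line S_220 and from different flowcells, had a base-pair Jaccard index of 0.548, whereas EF replicates 2 and 4, both line S_221, had 0.285, less than EF replicate 2 had with EF replicate 1 (0.330) or Wt replicate 3 (0.297). Unequal list lengths lower this index, and by containment 96.9% of the regions of EF replicate 2 were called in EF replicate 4, against 79.4% in EF replicate 1 and 81.9% in Wt replicate 3. Wt_IGF1 had an index of 0.554 with Wt replicate 4 and of 0.526 with Wt replicate 3 of its own line name, and it called 82.3% and 94.4% of their regions. The index averaged 0.293 over pairs of the same genotype and 0.277 over pairs of an EF and a Wt library. The difference of 0.0166 was reached by 10 of the 35 splits of the 8 libraries into groups of 4 (exact permutation test, p = 0.286) and by 2 of the 18 splits balanced by flowcell. Within flowcell BSF_1013 it was 0.0316. The sign turned with the EF libraries merged by line (-0.0438) and without EF replicate 1 (-0.0259) or EF replicate 3 (-0.0194). The closest pair of the series was EF_IGF1 replicate 1 and EF_IGF1 replicate 2 (0.639), although their titles name lines S_220 and S_221. EF_IGF1 replicate 1 shared 0.581 with EF replicate 4 (line S_221) and 0.375 with EF replicate 3 (line S_220), the line of its own title. Directions below that use EF_IGF1 replicate 1 are therefore given for the library labelled line S_220.

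**Figure D1:**
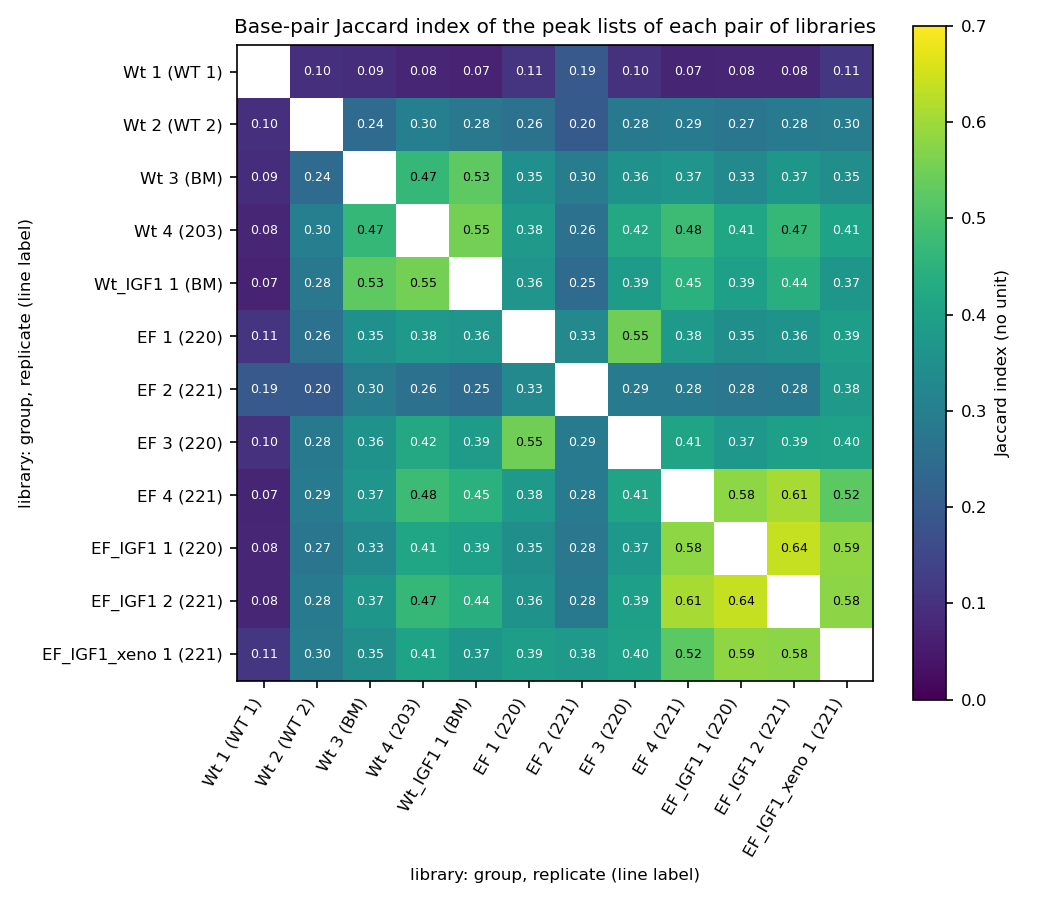
Base-pair Jaccard index (shared bases over all covered bases, no unit) of the peak lists of each pair of the 12 libraries, named by group, replicate and line. EF_IGF1 replicates 1 and 2 have the highest index (0.639), and Wt replicate 1, with 7748 peaks, the lowest values throughout, at most 0.195.

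The comparison of EF with Wt asks which regions differ in openness in cells carrying the EF genotype. Regions gained in EF, called in at least 3 of 4 EF and in no Wt library, numbered 1824, and regions lost in EF, the mirror of that rule, numbered 1439. Cobl, an actin nucleator, and Negr1, a neuronal adhesion molecule of the immunoglobulin family, held 6 gained regions each and no lost one. Dusp22, a dual-specificity phosphatase, Iqsec1, an exchange factor for Arf6, and Rftn1, a lipid raft protein of B cells, held 4 lost regions each. Gained regions lay near a gene end in 4.55% of cases and lost regions in 11.9%. Of the 35 splits of the 8 libraries, 15 had at least 1824 regions in their larger direction, 7 had at least 3263 in both directions together, and the real split alone had 1439 in its smaller direction (highest other 1216). Among the 18 splits with 2 libraries of each flowcell on each side, 5 reached the larger direction and only the real one the sum (highest other 2576). Over the 35 splits the smaller direction fell as mean peaks per library differed more (Spearman correlation -0.568). Only 2 splits differed less than the real one (1158 peaks), and these had 59 and 74 regions in their smaller direction. Like list lengths alone thus did not give a value near 1439, though the rank of the lost regions may in part follow list length.

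Among the other genes with most gained regions, Bcar3, an adaptor that binds p130Cas, had 5, and Pde4b, a phosphodiesterase of cAMP, had 5 against 1 lost. Adgrl3, an adhesion G protein-coupled receptor of the latrophilin family, Agbl4, a cytosolic carboxypeptidase, and Col18a1, the collagen from which endostatin is released, had 4 each. The taurine transporter Slc6a6, the syntrophin Sntg2 and Sybu, a kinesin adaptor, also had 4 each. The strongest of these regions lay inside Cobl (chromosome 11, 12434615 to 12435508), inside Adgrl3 (chromosome 5, 81275281 to 81276130) and inside Sybu (chromosome 15, 44711380 to 44712059). Lost regions numbered 3 each at Calcb, a calcitonin gene-related peptide, Carmil1, a regulator of actin capping, Gcnt2, a glucosaminyltransferase, Gsap, Larp4b, Mamdc2 and Mki67, the proliferation marker Ki-67. The strongest lost region of Calcb lay 5854 bp outside the gene (chromosome 7, 114710217 to 114711185).

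No fixed gene list differed between gained and lost regions after adjustment over 20 lists by Fisher's exact test on regions, and 1 of them, the hematopoietic markers, had an unadjusted p under 0.05. That list held 0 of the 1824 gained and 7 of the 1439 lost regions (Fisher's exact test, p = 0.00322, adjusted p = 0.0644), at Ptprc (the leukocyte antigen CD45), Csf1r (the receptor of macrophage colony-stimulating factor) and Ikzf1 with 2 each and Cd3e with 1. With genes as units, against 10000 random lists with as many regions, its adjusted p was 0.004. Blood markers stood apart in Wt replicate 2: 77.8% of the regions of the hematopoietic list were called there, against 6.06% to 30.3% in the other 11 libraries. The same library called 19.8% of the regions of the mesenchymal stem and limb list, against 38.9% and 47.7% in Wt replicates 3 and 4. Against Wt replicates 3 and 4 only, the hematopoietic list held 1 of 2287 gained and 6 of 6225 lost regions (Fisher's exact test, adjusted p = 0.975).

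**Figure D2:**
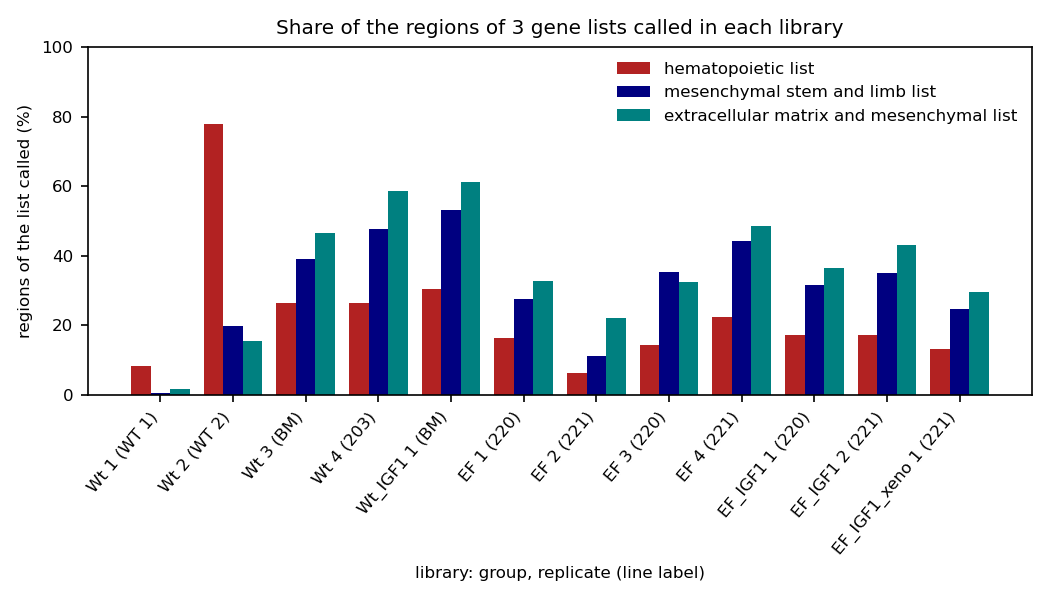
Percent of the regions of the hematopoietic, the mesenchymal stem and limb, and the extracellular matrix and mesenchymal list called in each of the 12 libraries (group, replicate, line); bars start at 0 and carry no error, each being 1 library. Wt replicate 2 calls 77.8% of the hematopoietic regions, and 15.5% of those of the matrix list.

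The lists of the Ewing sarcoma field held few regions in either direction, and values are given without a call. EWS::FLI1 targets of human Ewing sarcoma held 1 gained region, at the cyclin gene Ccnd1, and 4 lost ones, including 1 each at Cav1, Myc and Sox6. YAP and TEAD targets held 8 gained regions, 2 of them at Crim1 and 1 each at Amot and Amotl1, and 5 lost ones, 2 of them at Asap1. The Hippo core held 5 and 2, with 2 gained regions inside or near Tead1, the DNA-binding partner of YAP1, and 1 at the kinase gene Stk3. The IGF pathway held 3 and 4, with 2 gained regions at the insulin receptor gene Insr and 1 lost region at Akt1. Yap1, Igf1, Igf1r, Nkx2-2 and Cdkn2a had no gained and no lost region, and Nr0b1, a classic target of the fusion in human tumours, had no region in any library.

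Lineage lists were also thinly covered. Osteogenic genes held 2 gained regions, at Sp7 (the osteoblast factor osterix) and Mepe, and no lost one. Chondrogenic genes held 2 and 4, with 2 lost at Trps1, and adipogenic genes 2 and 4, with 2 lost at Cebpb and 1 at Fabp4. The mesenchymal stem and limb list held 4 gained regions, 2 of them at Thy1 and 1 at Prrx1, the limb mesenchyme factor, and 1 lost region at Cd44. Posterior HOX genes held 2 and 0 (Hoxb9 and Hoxc13) and anterior HOX genes 0 and 1 (Hoxb5). Extracellular matrix genes held 2 and 4, with 2 lost at the collagenase gene Mmp13, and inflammatory and AP-1 genes 2 and 4, with 1 lost each at Fos and Atf3. Tumour suppressors and cell cycle genes held 1 and 2 (Rb1 gained, Cdk6 and Nf1 lost), and WNT, SHH and BMP genes 2 and 2. Markers of smooth muscle and pericytes held 3 and 0, epithelial markers 2 and 1, endothelial markers 1 and 2, muscle markers 1 and 0, and neural markers none.

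The balance of gained and lost regions differed between the flowcells: 2935 against 7008 on BSF_1013 and 6271 against 751 on BSF_0654. On BSF_0654 a lost region had to be called in Wt replicate 1, with its 7748 peaks. The Wt line names also differed between the flowcells, so flowcell and Wt culture cannot be told apart. On BSF_1013 alone 3 lists passed. There, osteogenic genes held 6 gained and 1 lost regions (adjusted p = 0.0345), posterior HOX genes 5 and 0 (adjusted p = 0.0345) and extracellular matrix genes 4 and 34 (adjusted p = 0.0492), by Fisher's exact test; none had an adjusted p under 0.05 with genes as units. Leaving out 1 library (and then asking for 3 of 3) gave 317, 528 and 277 gained regions without EF replicates 1, 3 and 4 and 3759 without Wt replicate 4. It gave 2691 lost regions without EF replicate 4 and 87, 126 and 141 without Wt replicates 2, 3 and 4, where the rule requires a call in Wt replicate 1 with its 7748 peaks, against 1346 without Wt replicate 1.

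Libraries that took no part in the definition were read at the same regions. Of the 1824 gained regions, 58.9% (95% Clopper-Pearson interval 56.6 to 61.2) were called in EF_IGF1 replicate 1, 56.5% (54.2 to 58.8) in EF_IGF1 replicate 2, 46.8% (44.5 to 49.1) in EF_IGF1_xeno and 36% (33.8 to 38.2) in Wt_IGF1. Of the 1439 lost regions, 10.8%, 20.2% and 5.42% were called in the EF_IGF1 libraries and in EF_IGF1_xeno, and 92.2% (90.7 to 93.5) in Wt_IGF1. Of all regions, 36.8%, 39.5%, 26.7% and 51.9% were called in EF_IGF1 replicates 1 and 2, EF_IGF1_xeno and Wt_IGF1. Wt_IGF1 called 94.4% and 82.3% of all regions of Wt replicates 3 and 4, so its 92.2% is not particular to the lost regions. Of all regions of single EF libraries, EF_IGF1 replicate 1 called 61.2% to 87.8%, EF_IGF1 replicate 2 64.1% to 91.4% and EF_IGF1_xeno 51.7% to 84.3%. Wt_IGF1 called 72.8% to 91.6% of them. The shares of the gained regions lay below these ranges, with the widest gap in Wt_IGF1. Intervals cover counting error only, and the same line names recur in these libraries.

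**Figure D3:**
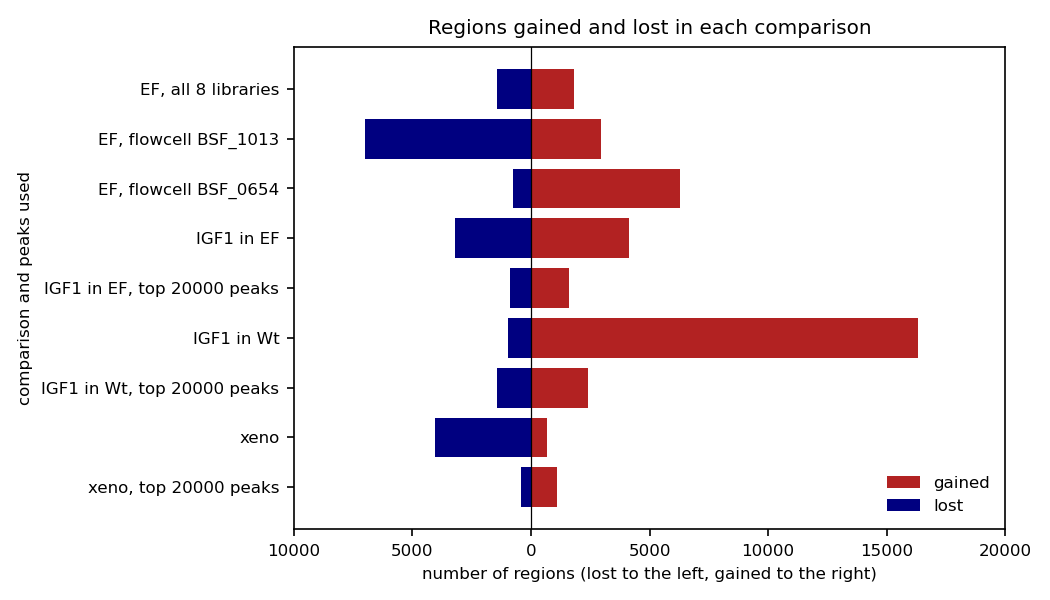
Number of regions gained (right) and lost (left) in each comparison, with other choices of flowcell or peaks below it; bars start at 0. EF has 1824 gained and 1439 lost regions over all 8 libraries, and 2935 and 7008 on flowcell BSF_1013.

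The comparison of EF_IGF1 with EF, within flowcell BSF_1013, asks what accompanies IGF1 in EF cells. Regions called in both EF_IGF1 libraries and in neither EF library (gained) numbered 4135, and regions called in both EF libraries and in neither EF_IGF1 library (lost) numbered 3191. Gained regions clustered at Arhgap42 with 19 and at Gabbr2, a subunit of the GABA-B receptor, with 11. Lost regions were most frequent at Arhgap26 (10, against 2 gained), Trabd2b, a metalloprotease that inactivates WNT ligands (9), and Prickle2, of the planar cell polarity pathway (8). Adipogenic genes were the list that differed between the directions: 21 of the gained and 1 of the lost regions (Fisher's exact test, adjusted p = 0.00205). With 2 libraries against 2 the counts themselves carry no test.

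The adipogenic regions gained with IGF1 lay at 8 genes. Cebpb, an early transcription factor of fat cell differentiation, held 5, Lep, the gene of the hormone leptin, 4, Zfp423, a factor of preadipocyte commitment, 4, Lpl, lipoprotein lipase, 3, and Pparg, the master regulator of adipogenesis, 2. Ebf1, Ebf2 and Klf15 held 1 each, and the lost region was at Ebf2. The strongest regions lay 52286 bp outside Cebpb (chromosome 2, 167742496 to 167742939), inside Lep (chromosome 6, 29073448 to 29073813), inside Zfp423 (chromosome 8, 87692588 to 87693252) and 47212 bp outside Lpl (chromosome 8, 68953825 to 68954462). With genes as units the adjusted p was 0.024. In line S_221 alone, which leaves out the library labelled S_220, 41 of 12343 gained and 25 of 16684 lost regions were adipogenic (Fisher's exact test, adjusted p = 0.033; 0.193 with genes as units). These regions lay at 8 genes with gained and 10 with lost regions. EWS::FLI1 targets (44 and 31) and anterior HOX genes (13 and 4) also passed there by Fisher's exact test, each with an adjusted p of 0.0449, and neither did with genes as units.

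Of the other lists, 3 had an unadjusted p under 0.05 by Fisher's exact test on regions and none passed the adjustment. These were the mesenchymal stem and limb list, posterior HOX genes and the WNT, SHH and BMP list, with adjusted p-values of 0.133, 0.141 and 0.172 by that exact test. The mesenchymal stem and limb list held 2 gained and 9 lost regions, 3 of the lost ones at Prrx1 and 1 each at Cd44 and Cxcl12. Posterior HOX genes held 7 and 0, at Hoxc13 (2), Hoxb9, Hoxb13, Hoxc9, Hoxc12 and Hoxd13, and anterior HOX genes 5 and 0, including 2 at Hoxb6 and 1 each at Hoxa7, Hoxb7 and Hoxd3. WNT, SHH and BMP genes held 10 and 18, with the hedgehog effector Gli2 at 1 and 4, Gli3 at 3 and 1, and Bmp7 at 3 and 1. Extracellular matrix genes held 10 and 17, with 2 lost at the cadherin gene Cdh11. Osteogenic genes held 5 and 7, chondrogenic genes 9 and 4, inflammatory and AP-1 genes 6 and 6, and tumour suppressors and cell cycle genes 7 and 1. Hematopoietic markers held 1 and 2, endothelial 3 and 4, muscle 3 and 0, epithelial 4 and 2, neural 3 and 2, and smooth muscle and pericyte markers 1 and 3.

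EWS::FLI1 targets held 16 gained and 7 lost regions, 4 gained each at the kinase genes Prkcb and Vrk1 and at Sox6. YAP and TEAD targets held 17 and 14, with Crim1 at 4 and 0 and the RNA-binding protein gene Rbms3 at 0 and 5. The Hippo core held 7 and 4, with Wwtr1 (TAZ, the paralog of YAP1) and Vgll4 at 2 and 2 each. The IGF pathway held 11 and 8, with the adaptor gene Irs2 at 3 and 0 and Insr at 0 and 2. Igf1 and Igf1r each lost 1 region, Cdkn2a had no gained and no lost region, and the gained region of Nkx2-2 (chromosome 2, 147133906 to 147134140) was called in the 2 EF_IGF1 libraries only. Further gained regions fell at Pax2, a paired-box factor of kidney development, Cpne8, Igsf21, Slc24a3, St6galnac3 and Tafa5 (6 each) and at Astn2 and the calcium pump gene Atp2b2 (5 each). Further lost regions fell at Atxn1 and Galnt17 (7 each), Setbp1, the actin bundler gene Pls3, Pde4d and the retinoic acid receptor gene Rarb (6 each), Aig1 (5) and the cyclooxygenase gene Ptgs2 (3).

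The balance of gained and lost regions depended on the libraries used. In line S_221 alone lost regions outnumbered gained ones, 16684 against 12343, as they did without EF replicate 3 (12911 against 4896), and leaving out 1 library at a time gave 10465, 9738 and 17278 gained regions without EF_IGF1 replicates 1 and 2 and EF replicate 4. The lost count was 5595 without EF_IGF1 replicate 2 and 12911 and 16041 without EF replicates 3 and 4. Each of these settings asks for a call, or for none, in fewer libraries, so its counts could only rise. The regions gained with IGF1 were called in EF_IGF1_xeno in 47.3% of cases (95% Clopper-Pearson interval 45.7 to 48.8) and in Wt_IGF1 in 33.3% (31.9 to 34.8), against 18.7% and 23.4% in Wt replicates 3 and 4. EF_IGF1_xeno called more, 67.2% and 62.5%, of all regions of EF_IGF1 replicates 1 and 2. The lost regions were called in 5.77% of cases in EF_IGF1_xeno and in 69.9% in Wt_IGF1, against 48.0% and 63.8% in Wt replicates 3 and 4. Regions of both directions were thus called more often in Wt_IGF1, which called 51.9% of all regions, against 35.3% and 43.7% in Wt replicates 3 and 4.

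Yap1, on chromosome 9, held 21 regions, none of them gained or lost with IGF1 in EF. The region at its gene end (8003114 to 8005434) was called in 10 libraries, all but Wt replicates 1 and 2. Another region inside Yap1 (7965462 to 7966205) was called in EF replicates 2 and 4, both EF_IGF1 libraries and EF_IGF1_xeno, and in no Wt library. By contrast, 3 regions inside the gene (starting at 7943962, 7950191 and 7961682) were called in Wt replicates 3 and 4 and in Wt_IGF1 only. These regions were singled out after their values were seen. At Cdkn2a, the tumour suppressor locus of p16 and p19ARF, the region near a gene end (chromosome 4, 89294380 to 89295669) was called in EF replicates 1 and 3, the 4 Wt libraries and Wt_IGF1, and in neither an EF_IGF1 library nor any library of line S_221.

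The local background of peaks around Yap1 was raised in 3 libraries. In a block of 2.25 Mb (chromosome 9, 7750001 to 10000000) that holds Tmem123, Birc2, Birc3, Yap1, Cfap300, Cep126, Trpc6, Pgr, Arhgap42 and Cntn5, the median background of a peak was 5.59 times the genome background in EF_IGF1 replicate 1, 6.38 times in EF_IGF1 replicate 2 and 7.0 times in EF_IGF1_xeno. The other 9 libraries had at most 2.06 times. EF replicate 4, the library of line S_221 without IGF1 on the same flowcell, had 1.72 times. The block held 41 of the 4135 regions gained with IGF1, and all 19 at Arhgap42 belong to a gene of the block. Without the block, 4094 gained and 3190 lost regions remained.

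**Figure D4:**
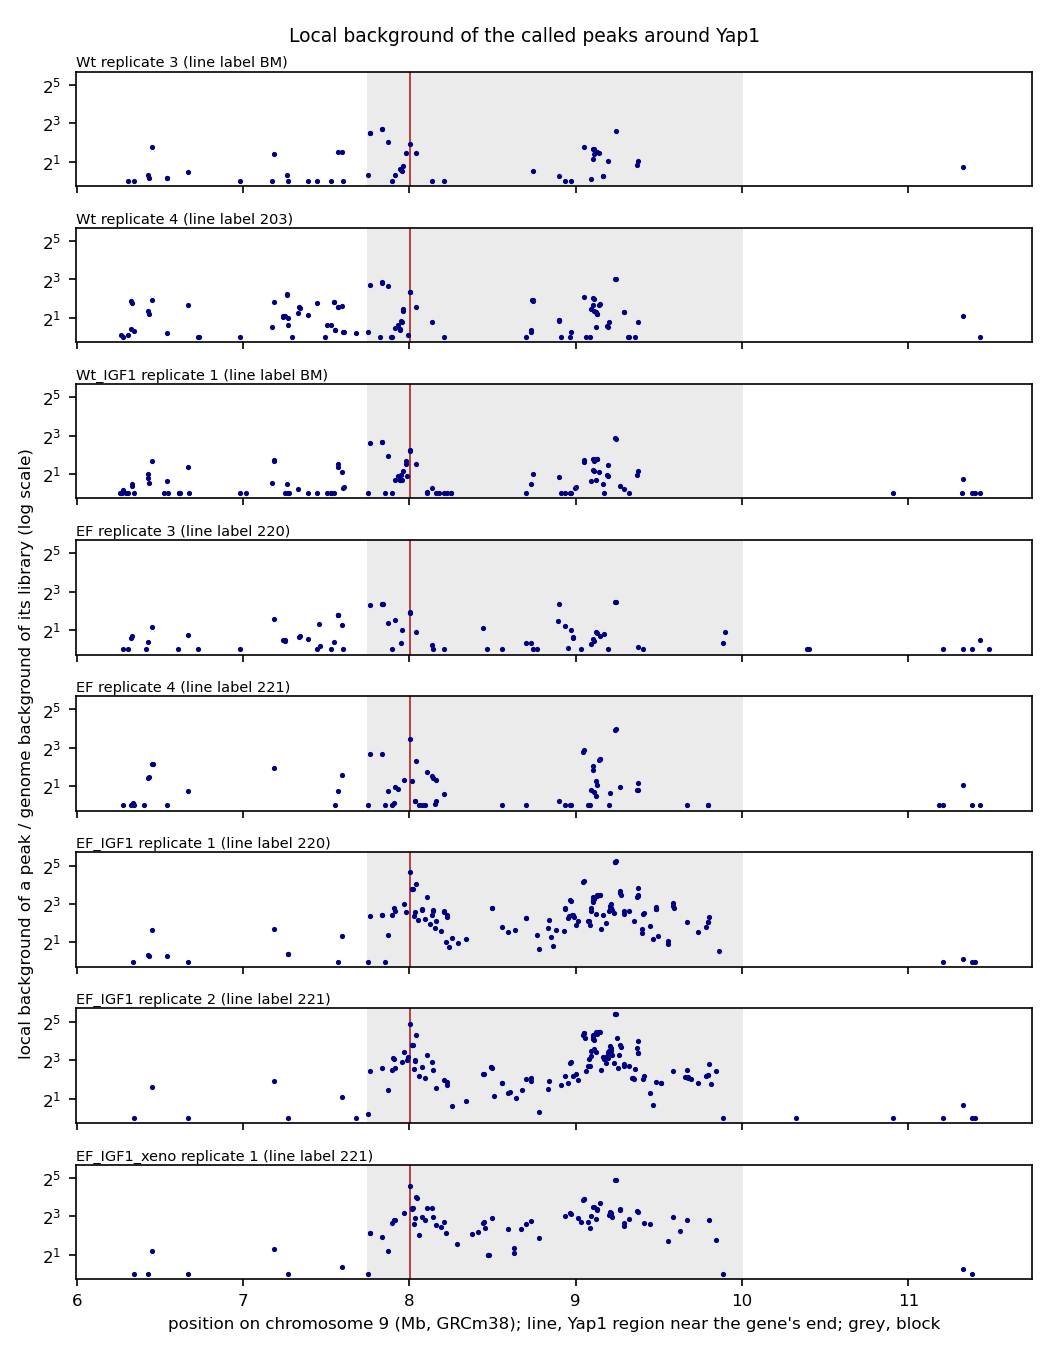
Local background of each called peak relative to the genome background of its library (log axis, no unit) along chromosome 9 (Mb, GRCm38), 1 panel for each of the 8 libraries of flowcell BSF_1013; the grey block runs from 7.75 to 10 Mb and the line marks the Yap1 region at the gene end. In EF_IGF1 replicates 1 and 2 and EF_IGF1_xeno the medians in the block are 5.59, 6.38 and 7.0, and in the other libraries at most 2.06.

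In wild-type cells the library with IGF1 was compared with Wt replicates 3 and 4 of the same flowcell, with no replicate of the treated side. Regions gained numbered 16308 and regions lost 957. Gained regions were most frequent at Rbms3 (23, against 1 lost), Pde4d (19), Prkg1, a cGMP-dependent kinase, Zbtb20, a zinc finger repressor, and Kcnma1, the large-conductance calcium-activated potassium channel (16 each, with 2 lost at Kcnma1). Lost regions reached 3 at Megf6 (0 gained), Septin9 (2 gained), and Aopep, Pik3r1 (the regulatory subunit of PI3-kinase) and Thsd4 (4 gained each). Among list genes, Tead1 held 8 gained and 1 lost regions, Igf1r 10 and 1, Igf1 5 and 0, the WNT antagonist gene Dkk2 7 and 0, Yap1 3 and 0, and the bone genes Alpl, Dlx5 and Runx2 4 and 0 each. Cdkn2a held 1 gained and Nkx2-2 1 lost region, and Prrx1 had no gained and no lost region. No list passed the adjustment over 20 lists by Fisher's exact test, and 3 had an unadjusted p under 0.05: EWS::FLI1 targets with 30 gained and 7 lost regions, adipogenic genes with 25 and 6, and extracellular matrix genes with 44 and 7. The share of each was lower among gained than among lost regions (0.184% against 0.731%, 0.153% against 0.627% and 0.27% against 0.731%). For adipogenic genes this is opposite to the direction in EF, but it rests on 6 lost regions. The percent of adipogenic regions called was higher with IGF1 in both, by 12.7 and 6.15 points against EF replicates 3 and 4 and by 13.5 and 10.4 against Wt replicates 3 and 4. Over all regions the change was 3.91 and -2.83 points in EF and 16.5 and 8.20 in Wt. The difference from EF was not tested. With genes as units no list passed either.

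The gained count was lower with shorter peak lists. With as many top peaks per library as in the shortest of the 3 lists, 5721 regions were gained and 3077 lost, and with the top 20000 peaks of each library 2420 and 1423. Against the Wt library of the same line name, BM, alone, 28354 were gained and 3033 lost.

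The xeno label marks 1 library of line S_221, compared with the 4 EF and EF_IGF1 libraries of its flowcell. Regions called in it and in none of the 4 (gained) numbered 663, and regions called in all 4 and not in it (lost) 4027. Trpc6, a calcium-permeable channel inside the block of raised background around Yap1, held 7 gained regions and 1 lost one, and Cntn5, in the same block, 2 gained. Irs2, the insulin receptor substrate, Tafa5 and Slc25a48 held 3 gained each, and the hedgehog effector Gli2, Adamts16, Arhgef19, Epb41l4a and Fbxl2 2 each. Lost regions were most frequent at Kalrn, the gene of kalirin (11), Abr (6), and Anks1, Ece1 (endothelin-converting enzyme), Stim1 (the calcium sensor of the endoplasmic reticulum), Ttc28 and Zbtb7c (5 each). Adenosine kinase Adk, Chchd3 and the kinase Csk, which inhibits Src kinases, held 4 lost regions each.

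Among fixed lists, tumour suppressor and cell cycle genes held 0 gained and 10 lost regions, 4 of them at Nf1, a negative regulator of RAS, 3 at the cyclin gene Ccne1, 2 at Cdk6 and 1 at Cdkn2a. The Hippo core held 2 and 6, with 3 lost at Tead4 and 2 at Tead1, and YAP and TEAD targets 0 and 5, with 1 each at Ccn1, Ankrd1, Ajuba and Arhgef17. Osteogenic genes held 1 and 9, with 2 lost at Col1a2, the mesenchymal stem and limb list 1 and 9, with 3 lost at Meox1, and the IGF pathway 4 and 5. With 663 gained and 4027 lost regions in all, such counts lean to loss. As shares, the Hippo core (0.302% of gained against 0.149% of lost regions) and the IGF pathway (0.603% against 0.124%) lay higher among gained regions. The shares of the other lists named here were higher among lost regions. Igf1r held 1 gained and Prrx1 1 lost region, and Yap1, Igf1 and Nkx2-2 had no gained and no lost region. By Fisher's exact test on regions no list passed the adjustment over 20 lists, 1 (the IGF pathway) had an unadjusted p under 0.05, and none passed with genes as units. The xeno library had the fewest peaks of its flowcell, 43416, and with the top 20000 peaks of each library the balance turned, to 1111 gained and 435 lost. Against EF_IGF1 replicate 2 alone, 3040 regions were gained and 22715 lost.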

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

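All comparisons in this part were chosen only after the values were seen. Of 54 sets of 4 values of the EF or Wt group examined for a library far from the other 3, 3 had one, and chance gives about 1 in 20. In Wt replicate 1, 67.6% of summits lay within 1 kb of a gene end, against 18.8% to 21.0% in the other Wt libraries. Of the regions of the endothelial marker list 0.741% were called in Wt replicate 1, against 34.8% to 40% in the other Wt libraries. Both values belong to the library with the fewest peaks, 7748. EF replicate 2, with the fewest peaks of its group (27332), called 12.4% of the regions of the WNT, SHH and BMP list, against 34.0% to 35.5% in the other EF libraries.

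Lists were considered only if the percent of their regions called moved the same way with IGF1 in both EF pairs. This left out neural markers (3.33 and -10 points), for example. With IGF1, the percent of regions called moved in opposite directions in EF and in Wt for 3 lists. For WNT, SHH and BMP genes it fell by 5.58 points on average in EF (by 6.85 in the pair labelled S_220 and 4.31 in line S_221) and in Wt was 20.8 points higher with IGF1 than in Wt replicate 3 (BM, its own line name) and 7.87 points higher than in Wt replicate 4. For endothelial markers it fell by 6.30 points in EF (by 2.96 and 9.63) and in Wt was 11.1 and 5.93 points higher. For the mesenchymal stem and limb list, which holds Prrx1, it fell by 6.54 points in EF (by 3.89 and 9.19) and in Wt was 14.1 and 5.30 points higher. Over all regions the change was 3.91 and -2.83 points in EF and 16.5 and 8.20 points in Wt, so in Wt the endothelial, the mesenchymal and, against Wt replicate 4, the WNT values lay below that of all regions. The difference between EF and Wt was not tested, and the Wt library with IGF1 had the longest peak list of the series, 83718 peaks.

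Chromosome Y was not used in the comparisons. Peaks in its short arm, ending before 4 Mb, numbered 5 in Wt replicate 3, 7 in Wt_IGF1 and 11 in Wt replicate 4, and 0 in each of the other 9 libraries, Wt replicates 1 and 2 included. The sex of the animals is not given in the sources used here. On flowcell BSF_1013 every Wt and Wt_IGF1 library had such peaks and no EF library did. Genotype and the presence of these peaks thus cannot be told apart there, and chromosome X was kept in the comparisons.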

How the results depend on the processing

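Each result was recomputed under other settings, giving 149 values: 98 were counted as unchanged, 43 as moved and 8 as changed in sign. A count of regions was unchanged within 1.5 times its main value. Differences in peaks per library, gene-end share and Jaccard index were unchanged if they kept their sign and test result, even where their size changed. The difference in peaks, for example, was 1158 in the main setting and 8708 without EF replicate 2. The adipogenic list was unchanged if it passed again. The restrictions to Wt replicates 3 and 4 and to line S_221, equal list lengths for IGF1 in Wt, genes as units, and the removal of the block around Yap1 were added after the data had been seen. The cause of these shifts was not tested.

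With the top 20000 peaks per library, EF lost 403 regions, IGF1 in EF gave 1587 gained and 867 lost, IGF1 in Wt 2420 gained, and the xeno library 1111 gained and 435 lost. Within flowcell BSF_1013, EF against Wt gave 2935 gained and 7008 lost regions, and within BSF_0654 6271 and 751. On BSF_1013 the difference in peaks per library turned from 1158 to -3432, and that in summits near gene ends from -8.09 to 0.896 percentage points. Asking for 4 of 4 against 0 of 4 left 257 gained and 87 lost regions. The mean share of EF-gained regions called in the EF_IGF1 and EF_IGF1_xeno libraries was then 71.5%, against 54.1% by the rule used, and 85.2% for regions of BSF_0654 alone.

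Merging the EF libraries by line gave 3871 gained regions and a Jaccard difference of -0.0438 instead of 0.0166. Against Wt replicates 3 and 4 only, 6225 regions were lost. Treating the line names as a replicate block left IGF1 in EF at 4135 and 3191 regions, which is the same by construction, since both pairs had to differ. Line S_221 alone gave 12343 gained and 16684 lost regions. IGF1 in Wt gave 5721 and 3077 with lists of equal length and 28354 and 3033 against the BM library alone. The xeno library against EF_IGF1 replicate 2 alone gave 3040 and 22715. Line S_221 alone, BM alone and EF_IGF1 replicate 2 alone put fewer libraries into the rule, so these counts could only rise.

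Leaving out 1 library at a time (and asking for 3 of 3 in its group), EF-gained regions ran from 277 (without EF replicate 4) to 3759 (without Wt replicate 4) and EF-lost regions from 87 (without Wt replicate 2) to 2691 (without EF replicate 4). With IGF1 in EF, gained regions ran from 4896 (without EF replicate 3) to 17278 and lost regions from 4282 (without EF_IGF1 replicate 1) to 16041, the highest of both without EF replicate 4. There the rule was loosened to the libraries left, so these counts could only rise. The difference in peaks per library ran from -12534 (without Wt replicate 1) to 8708 (without EF replicate 2), and was -4628 without EF replicate 4. That in summits near gene ends ran from -12.4 (without Wt replicate 4) to 3.83 points (without Wt replicate 1). The Jaccard difference ran from -0.0259 (without EF replicate 1) to 0.0570 (without Wt replicate 4), and was -0.0194 without EF replicate 3.

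Among the gene lists, 1 passed for IGF1 in Wt against other regions called in as many libraries, 2 for IGF1 in EF with genes within 250 kb, 3 for EF on flowcell BSF_1013, 1 for EF with genes as units and 3 for IGF1 in EF in line S_221. The adipogenic list with IGF1 in EF passed in all 5 of its alternatives (adjusted p from 1.07e-05 to 0.033), but not in line S_221 with genes as units (0.193). Motif shares and their alternatives were not run, as they need the genome sequence, and the settings that name a transcription start used the gene interval or gene end instead.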

Other observations

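The tests in this part were chosen only after the result they measure was seen, except the ranks of the gained regions, the lost regions and the Jaccard difference among all splits, the second list of blood genes, the search for a mixture of lines and the reads at the summits around Yap1. For the ranks, which direction to compare and the restriction to splits balanced by flowcell were also chosen after. The EF libraries came from 2 lines, so no result here separates the EF genotype from differences between lines.

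Between EF and Wt, chance could not be excluded over all 35 splits for the gained regions, for the sum or for the Jaccard difference. In the larger direction 15 splits reached the real 1824 (highest other 6222), for the sum 7 reached 3263 (highest other 6242), for Jaccard 10 reached 0.0166 (highest other 0.0495), and the smaller direction, the 1439 lost regions, was reached by the real split alone (highest other 1216), 1 of 4 counts and chosen after the values were seen. The smaller direction also tended to be larger in splits with like list lengths, as the real one has. The 2 splits with a smaller difference in mean peaks had 59 and 74 regions there, so like list lengths alone did not give the real value. List length may still have added to its rank. The split by flowcell gave 5081 and 18 regions and a Jaccard difference of 0.0421, and both short lists, Wt replicate 1 (7748 peaks) and EF replicate 2 (27332), are on BSF_0654. The 18 splits with 2 libraries of each flowcell on each side are too few for a share under 0.05; among them the highest other value was 2354 for the larger direction, 1216 for the smaller, 2576 for the sum and 0.0229 for Jaccard. Within flowcell BSF_1013 2935 regions were gained and 7008 lost.

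Wt replicate 2 called most regions of several blood genes, such as 6 of 6 at Adgre1 (the macrophage marker F4/80), 9 of 11 at Itgam and 10 of 12 at Spi1, the master factor of myeloid cells. At Spi1, however, Wt replicates 3 and 4 called 4 of 12 each. Their strongest peaks there ranked higher within their own lists (percentile 91.9 and 92.1, against 44.1 in Wt replicate 2). Regions merge the peaks of all libraries, and 22405 regions were called in Wt replicate 2 only (at most 7956 in any other library). Such regions raise its share of any list they fall in. Wt replicate 2 called 38.4% of all regions. A second list of 14 blood genes, chosen apart from the first, was called in 72.1% of its regions, against at most 34.3% in any other library. The length of its peak list does not account for this, as 0 of the 5 other marker lists were called most often in it, nor does the flowcell, whose EF libraries called at most 16.2% of the first list. A candidate explanation is that blood cells, macrophages among them, were part of that culture; whether the cells had been sorted is not given in the sources used here. Each region lost in EF was called in at least 3 of 4 Wt libraries. Blood cells in Wt replicate 2 alone thus do not account for the lost regions at Ptprc, Csf1r and Ikzf1. Against Wt replicates 3 and 4 only, the hematopoietic list held 6 of 6225 lost regions, and 7 of 1439 in the main comparison. Whether these losses reflect what the Wt cultures contained or the EF genotype cannot be told, and no biological explanation was tested.

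EF_IGF1 replicate 1 carries the name S_220 and shared more with line S_221. Of the regions called in both EF libraries of line S_220 and in neither of S_221, it called 8.39%, fewer than EF_IGF1 replicate 2 of line S_221 (12.3%) and than the Wt libraries of its flowcell (27.9% and 36.4%). A mixture of lines would raise that share, and among the 500 strongest of these regions the difference between the EF_IGF1 libraries was -9.2 percentage points. It called 68.9% of the regions private to line S_221, a share that does not mark that line, since Wt_IGF1 called 71.9% and EF_IGF1_xeno 61.0%, and with no second S_220 library with IGF1 a wrong line name and an effect of IGF1 on line S_220 cannot be told apart. If the name is wrong, the comparison of IGF1 in EF may rest on 1 line, and its 4135 gained and 3191 lost regions would then mix line and treatment.

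Around Yap1 the background was raised in both EF_IGF1 libraries and EF_IGF1_xeno. At 47 regions of the block called in EF_IGF1 replicate 2 and EF replicate 4, the reads at the summit, relative to the genome background and to the rest of the genome, were 3.49 times higher with IGF1 (2.27 times in EF_IGF1 replicate 1 and 3.26 times in EF_IGF1_xeno, against the same library). These reads were solved from the same peaks as the background by which the block was chosen. More open chromatin would raise them as well, so they do not separate it from more DNA copies. Of the 9 other libraries, 0 reached the lowest of the 3. The block was chosen by that difference, so this cannot exclude an effect of its sequence. The same rule was met by 0.335% of 4781 windows of the genome. The background is already relative to the genome background of each library, so this share says little about the number of reads. A candidate explanation is a gain of DNA copies from Tmem123 to Cntn5 in these cells, selected or present before IGF1, which these libraries cannot date. Regions gained at Arhgap42 with IGF1 may then follow from more template rather than from more open chromatin. Those gained at Trpc6 in the xeno library were called in neither EF_IGF1 library, although the background was raised there as well. A gain of copies shared by the 3 libraries would not by itself explain them.

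A second stretch of chromosome 9, from 53500001 to 54000000, with Atm, Npat and Cul5, had a median background of 8.29, 5.73 and 8.43 times the genome background in the same 3 libraries, and at most 3.93 in the others. The same rule was met by 7 single windows of 250 kb on chromosomes 3, 12, 14, 15 and 19, with the 3 libraries at 9.75 to 13.4 and the others at most 2.22 in the one starting at 105750001 on chromosome 14. Of the 16 windows in all, 9 lay on chromosome 9, and another set of 3 libraries reached 12. At Cdkn2a and Cdkn2b 7 successive regions among those called in at least 5 of the 7 libraries outside line S_221 and EF_IGF1 (chromosome 4, 89281998 to 89382072) had no call in the 4 libraries of line S_221 nor in EF_IGF1 replicate 1. Another run of 7 lay at Sox11, and 1837 of the 30407 regions so chosen (6.04%) had no call in those 4. Within the stretch at Cdkn2a, however, a region inside the gene (89286699 to 89287029) was called in EF replicate 4 and both EF_IGF1 libraries, so the stretch was not without calls there.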
